A study of Homo sapiens with 20 samples.

How the data were processed

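RNA of A549 cells was hybridised to Affymetrix arrays, 1 sample per array, 20 in all. Per the labels' protocols, parental and sorted cells were grown in RPMI medium with fetal bovine serum, and RNA was extracted with a Qiagen RNeasy kit. Silenced cells had been given lentivirus with the shRNA and sorted for the green fluorescent protein of the virus. The deposited values were log2 probe set summaries made by the authors with RMA, which corrects background, normalises between arrays and summarises probes, in Transcriptome Analysis Console 4.0, per the submitters' processing notes. The log2 unit was read from the values, 0.39 to 12.76, since no label states it. The probe definition library and genome build were not given. No detection calls or scanner files were used here, so signal over background was not assessed. No 2 arrays held identical values.

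Arrays were grouped by title and source name, 2 in each of 10 groups. The descriptions of the 4 silenced arrays of CD166-EpCAM- and CD166-CD44- cells call them stem cells, whereas their titles call them non-stem cells, and the titles were followed. Probe sets were named through the platform annotation and a RefSeq gene table of assembly GRCh38.p14 used for names alone. Of 53617 probe sets 16098 had 1 gene symbol, 0 had several and 37519 (70.0%) had none. All 16098 symbols were found in the reference by gene identifier and 0 were updated. Where a gene had several probe sets (779 genes) the one with the highest mean was tested, which left 14884 genes, 11916 of them protein-coding. No probe set was named RARB, and the receptor genes RARA and RARG were likewise not measured under their names.

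Differential expression was tested with limma 3.58.1 in R 4.3.3, with the data.table package, version 1.17.8. A linear model of the 10 group means over all 20 arrays (residual degrees of freedom 10, prior degrees of freedom 7.61) was moderated with eBayes, and p-values were two-sided and adjusted by the Benjamini-Hochberg method over the 14884 genes of a comparison, with 0.05 as the threshold. Mean effects weigh the 5 populations or both sorts equally, and an interaction is the silencing effect in stem cells minus that in non-stem cells. An F test in the same fit asked whether the silencing effects of the 5 populations differed. PNO1 and the sort marker genes were also tested by exact permutation of the silencing labels within populations. Chance overlap of calls is the product of both counts divided by the genes tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

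Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with camera at an estimated correlation and fry beside it. Of 29 lists, 26 with at least 5 measured genes were tested. Their subjects are those given for mean silencing. The lists of replication-dependent histones, stromal cells and red blood cells had 0, 3 and 1 measured genes and were not tested. Named genes were RARB, for which no value was had, PNO1, ALCAM, EPCAM and CD44. For each mean comparison the 10 highest and 10 lowest changes past the threshold with one sign in each population or sort were added. For each single comparison the 3 highest and 3 lowest past the threshold whose arrays did not overlap were added, without the overlap condition for interactions, which set no single pair of groups against each other. For each passing list the 4 members of smallest p were added, from which the text gives examples. Non-coding, clone, pseudogene, olfactory receptor and keratin-associated symbols were passed over in the naming by size. The groups, the tests of genes and lists, the lists, this rule and the alternatives were fixed before the data were examined. Chosen after seeing the data were cyclic loess normalization, the mean over 3 populations, the comparisons of populations by F test and likeness, the retests of single lists without 1 array, the permutation tests and the tests of explanations other than splits, that of PNO1 included.

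The alternatives were quantile normalization of the deposited values again, centring on array medians, only genes above the median level, every probe set, eBayes with trend and robust, array weights, only the arrays compared, a replicate block, a 2-fold threshold with and without adjustment, and each array left out in turn. The steps were tested on simulated data for 14884 genes with 200 changed by 0.5, 1 or 2 on the log2 scale. Recovered were 87.9%, 98.5% and 100% of them for mean silencing (6 false calls), 9.09%, 76.1% and 100% for silencing in parental cells (2), 31.8%, 94.0% and 100% for the mean stem difference (6) and 19.7%, 77.6% and 98.5% for the mean interaction (6).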

Results

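Transcript levels were measured on Affymetrix arrays in A549, a human lung adenocarcinoma line. Cells were unsilenced or silenced with lentivirus carrying a short hairpin RNA (shRNA) described as directed at RARB, the gene of retinoic acid receptor beta. Per the labels unsilenced cells were normal and non-silencing. No control virus was described, so silencing here may include effects of virus and its sort. Cells were taken unsorted, called parental, or as 4 populations sorted on surface proteins. The EpCAM sort separated CD166+EpCAM+ cells, described as putative cancer stem cells, from CD166-EpCAM- cells, described as putative non-stem cells. The CD44 sort separated CD166+CD44+ putative stem cells from CD166-CD44- putative non-stem cells. Each of the 5 populations had 2 unsilenced and 2 silenced arrays, 20 in 10 groups. The comparisons asked what silencing changed in each population and on average, how stem and non-stem cells differed without silencing, and whether silencing acted differently on them.

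The deposited values were on a log2 scale, with array medians from 2.77 to 2.93 and highest values from 12.63 to 12.76. Replicate arrays correlated across the 14884 genes tested with r from 0.983 to 0.993, and the standard deviation of their difference was 0.241 to 0.360 on the log2 scale. The number of arrays, 2 a group, limits the precision. The replicates were titled biological without mention of separate cultures, so p-values measure the spread between these arrays. Changes are log2 differences with the standard error (SE) of the fit after the sign ±, and adjusted p-values are from limma. Beside a gene list, a further number in the same parenthesis is the adjusted p of the list at a preset correlation between genes. Members counted over the list alone had p-values adjusted within the list.

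No probe set carried the symbol RARB in the annotation used, so the intended target was not checked on these arrays. The accession printed beside the target in the labels' protocol belongs to PNO1, a factor of small ribosomal subunit assembly. PNO1 differed by -0.29 ± 0.09 in the mean of the 5 populations (adjusted p = 0.0518), lower in 4 of 5, and missed the threshold. Its level was 7.22 ± 0.08 (SD, n = 2) in unsilenced and 6.56 ± 0.36 in silenced parental cells, and 6.29 ± 0.03 and 5.75 ± 0.21 in CD166-EpCAM- cells. The differences were -0.66 and -0.54 there, and 0.02, -0.20 and -0.09 in CD166+EpCAM+, CD166+CD44+ and CD166-CD44- cells (adjusted p = 0.0925, 0.101, 0.983, 0.552 and 0.872). An exact two-sided permutation test within populations, over 7776 labellings, gave p = 0.0149 for PNO1, or 0.0597 adjusted over PNO1 and the 3 sort marker genes. Over 29 other settings the PNO1 difference ranged from -0.35 to -0.21 and its adjusted p from 0.0232 to 0.311, past the threshold in 8.

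Transcripts of the sorted surface proteins did not pass the test between unsilenced sorted populations. ALCAM, the gene of CD166, differed by -0.16 ± 0.20 between stem and non-stem cells of the EpCAM sort and by -0.36 ± 0.20 in the CD44 sort (adjusted p = 0.81 and 0.466). EPCAM differed by -0.04 ± 0.22 in its own sort (adjusted p = 0.969) and CD44 by -0.47 ± 0.15 in its own (adjusted p = 0.14). Silenced minus unsilenced differences of ALCAM, EPCAM and CD44 were -0.17, -0.18 and 0.09 in the mean of the 5 populations, with exact permutation p-values of 0.191, 0.336 and 0.321 and 0.336 for each after adjustment.

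Averaged over the 5 populations, silencing lowered 667 genes and raised 168, 5.61% of those tested (adjusted p under 0.05). VCAN, the extracellular proteoglycan versican, fell by 1.25 ± 0.09 (adjusted p = 7.38e-07, n = 10 silenced and 10 unsilenced arrays), and the tetraspanin TSPAN7 by 1.18 ± 0.09 (adjusted p = 1.36e-06). NID2, the basement membrane protein nidogen 2, rose by 0.93 ± 0.09 (adjusted p = 1.44e-05). The other genes named by size, all with one sign in each population, were NUDT11 (-0.96), DCDC2 (-0.78), SDC2 (-0.74), PIEZO2 (-0.71), ADAM23 (-0.68), MLF1 (-0.68), NPNT (-0.67) and LIN7A (-0.66) among the lower, and ZNF850 (0.60), HRH1 (0.49), C1orf116 (0.46), CAMK2N2 (0.46), EFEMP1 (0.45), ASAH2 (0.44), ZNF304 (0.43), MCHR1 (0.43) and PLXNA3 (0.40) among the higher. SDC2 encodes the proteoglycan syndecan 2, PIEZO2 a mechanically gated channel, HRH1 the histamine H1 receptor and EFEMP1 the matrix protein fibulin 3. The VCAN difference ranged over populations from -2.99 in CD166-EpCAM- to -0.12 in parental cells, and a further VCAN probe set near the low end of the scale (mean 1.36) gave -0.08.

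Of the 26 lists tested, 12 passed, 9 of them lower, and 0 passed with an estimated correlation. Lower were G1/S genes of DNA replication (median -0.16, adjusted p = 9.23e-05), G2/M genes of mitosis (-0.19, 1.63e-05), ribosome biogenesis genes (-0.19, 5.64e-05) and cytosolic ribosomal proteins (-0.13, 0.000114). Their adjusted p was 0.188 to 0.282 with an estimated correlation. These means joined opposite signs, with medians of 0.45 for G1/S genes in CD166-CD44-, 0.54 for G2/M genes in parental, 0.19 for ribosome biogenesis in CD166+EpCAM+ and 0.14 for ribosomal proteins in CD166-CD44- cells. In these lists 2 of 24, 3 of 24, 2 of 21 and 2 of 25 measured members fell and none rose, or 7, 11, 10 and 4 over the list alone. The replicative helicase subunit MCM6 (-0.47), thymidylate synthase TYMS (-0.32), the kinetochore gene NDC80 (-0.41) and RPS15A (-0.43) were among them. Of 17 unfolded protein response and ATF4 targets 6 fell (adjusted p = 0.000728, and 0.188 with an estimated correlation), including the amino acid synthesis genes ASNS (-0.54), PSAT1 (-0.52) and PHGDH (-0.49), and 1 rose and 7 fell over the list alone. Of 11 NRF2 targets 4 fell (6 over the list alone, adjusted p of the list 0.000728), with SRXN1 at -0.34. Of 13 p53 targets 3 fell (4 over the list alone, 0.0125), with TIGAR at -0.40. Of 17 hypoxia and glycolysis genes 4 fell (1 rose and 6 fell over the list alone, 0.014), with PGAM1 at -0.39. Of 20 Wnt genes 4 fell (1 rose and 5 fell over the list alone, 0.042), with the receptor FZD6 at -0.36. These 4 lists had an adjusted p of 0.173 to 0.246 with an estimated correlation, and the p53 list passed as higher in CD166+EpCAM+ and CD166-CD44- cells.

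The lists that were higher were cell adhesion genes (adjusted p = 9.64e-05, and 0.173 with an estimated correlation), where 3 of 8 rose over all genes and over the list alone, namely CEACAM5 (1.26), CEACAM6 (0.81) and CEACAM1 (0.32, 0.0522 without unsilenced CD166+CD44+ replicate 1), and 2 lists without a called member. Parental cells carried most of these means (CEACAM5 4.97, CEACAM6 3.81). CEACAM5 was at -0.60 in CD166+EpCAM+ and -0.02 in CD166-CD44- cells, where CEACAM6 fell by 1.41 (adjusted p = 0.000133). The lists without a called member were cholesterol biosynthesis (median 0.09, 0.0249) and small nucleolar and Cajal body RNAs, a sign of RNA preparation (median 0.11, 0.042), adjusted p = 0.188 to 0.543 with an estimated correlation. Without silenced CD166+CD44+ replicate 2 the median of these RNAs was 0.0058 (adjusted p = 0.457). The lists of retinoic acid genes (0.556), stem cell genes (0.616), Notch (0.723) and Hedgehog signalling (0.105), epithelial (0.892) and mesenchymal genes (0.671), apoptosis regulators (0.443), interferon-stimulated genes (0.892), NF-kB and cytokine genes (0.118), oxidative phosphorylation (0.264), alveolar and club cell genes (0.614) and drug transporters (0.518) did not pass. Nor did the markers of leukocytes (0.0794) and endothelium (0.142). Members of these called over all genes were, higher, 1 each in the retinoic acid, mesenchymal, NF-kB and leukocyte lists and, lower, 2 in the Notch list and 1 each in the stem cell, Hedgehog, epithelial, mesenchymal, apoptosis and interferon lists. Over the list alone 2 each rose in the mesenchymal and NF-kB lists and 1 each in the retinoic acid, Hedgehog, leukocyte and endothelium lists. On the same basis 3 each fell in the Hedgehog and mesenchymal lists, 2 each in the Notch and epithelial lists and 1 each in the stem cell, apoptosis, interferon and NF-kB lists.

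In CD166-EpCAM- and CD166+CD44+ cells the change fell with a gene's mean level (r across genes -0.31 and -0.36, genes not being independent), from a median of 0.0616 and 0.117 in genes with mean values under 3 to -0.184 and -0.214 in those from 6 to 8, against r within ±0.0502 in the other populations. After quantile normalization the calls were 202 higher and 287 lower, after cyclic loess 228 higher and 281 lower, and over the 3 populations without these 137 higher and 124 lower. Over those 3 populations 3 lists passed, and MCM6, TYMS, NDC80, RPS15A, ASNS, PSAT1, PHGDH, SRXN1, TIGAR, HRH1, CAMK2N2, ASAH2, ZNF304, MCHR1, DCDC2 and CEACAM1 had adjusted p-values of 0.0532 to 0.953. After quantile normalization or cyclic loess TYMS (0.0703 and 0.102), TIGAR (0.0563 and 0.0534) and, after loess, SRXN1 (0.0607) lost their calls, as did the lists of Wnt (0.21 and 0.306), p53 (0.0635 and 0.0939) and hypoxia genes (0.051 and 0.117) and, after loess, NRF2 targets (0.0617). Leaving out single arrays ended the calls of the Wnt list (without any 1 of 9 arrays, adjusted p = 0.0543 to 0.107), the cholesterol list (without any 1 of 4 arrays, 0.0522 to 0.103) and the small nucleolar RNA list (without any 1 of 11 arrays, adjusted p = 0.0577 to 0.457). Leaving out 1 array moved the total of 835 to 510 and 392 without unsilenced parental replicates 1 and 2, 493 and 526 without unsilenced CD166+EpCAM+ replicates 1 and 2, 377 without silenced CD166+EpCAM+ replicate 2 and 544 without unsilenced CD166-EpCAM- replicate 2. Further totals were 468 without silenced CD166-EpCAM- replicate 1, 476 and 399 without unsilenced CD166+CD44+ replicates 1 and 2, 1294 without silenced CD166+CD44+ replicate 1, 553 without unsilenced CD166-CD44- replicate 2 and 397 without silenced CD166-CD44- replicate 2.

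**Figure D1:**
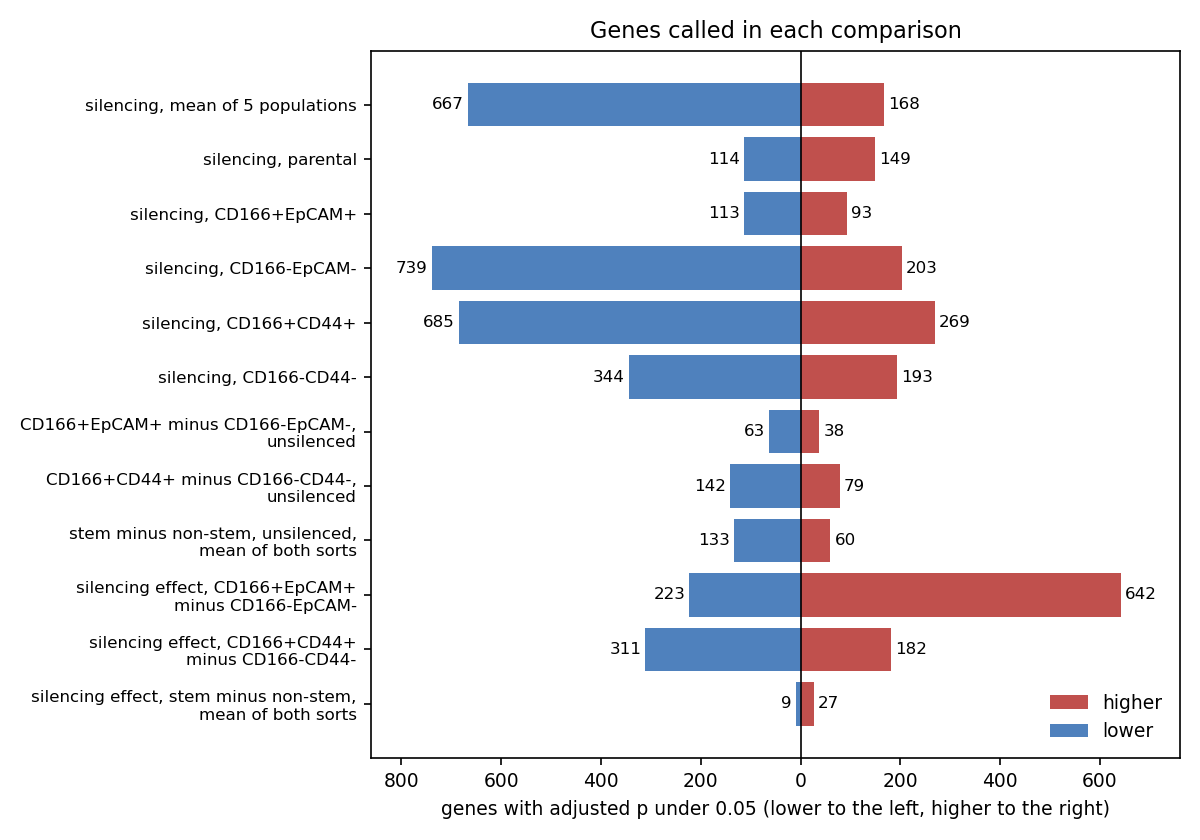
Number of genes (horizontal axis) higher and lower at an adjusted p under 0.05 in each of the 12 comparisons, as bars from 0. Silencing gave 739 lower and 203 higher genes in CD166-EpCAM- cells and 149 higher and 114 lower in parental cells.

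In parental cells silencing raised 149 genes and lowered 114. CEACAM5, the gene of carcinoembryonic antigen, rose by 4.97 ± 0.20 (adjusted p = 2.66e-11), from 4.76 ± 0.24 to 9.73 ± 0.08 (SD, n = 2 arrays each), and its paralog CEACAM6 by 3.81 ± 0.15 (adjusted p = 2.66e-11), from 6.52 to 10.33. Unsilenced sorted arrays all lay above unsilenced parental ones, at 5.22 to 10.08 (CEACAM5) and 8.83 to 10.24 (CEACAM6). FCGBP, a mucus-associated IgG Fc binding protein, rose by 2.24 ± 0.21 (adjusted p = 1.23e-05). TSPAN7 (-1.94 ± 0.21), the lipoxygenase gene ALOXE3 (-1.87 ± 0.21) and NECAB2 (-1.50 ± 0.19) fell, with adjusted p = 5.48e-05, 6.94e-05 and 0.000204. In the other populations the CEACAM5 difference was -0.60 in CD166+EpCAM+ (adjusted p = 0.167), 0.51 in CD166-EpCAM- (0.142), 1.44 in CD166+CD44+ (0.00106) and -0.02 in CD166-CD44- cells (0.981).

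**Figure D2:**
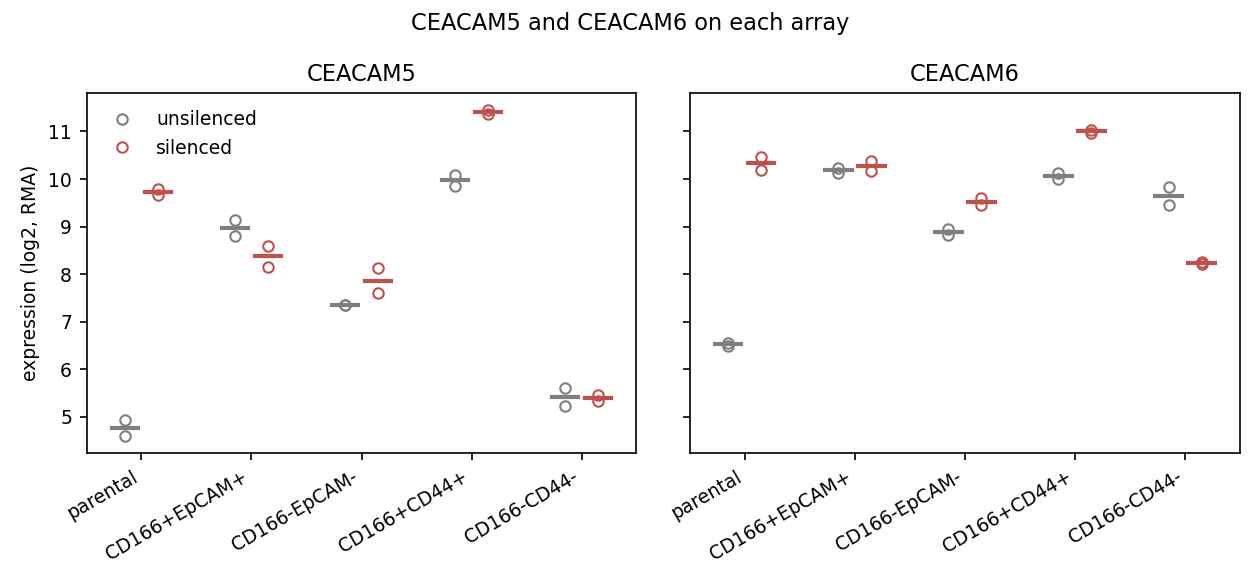
Log2 array values of CEACAM5 and CEACAM6 (vertical axes) in each of the 5 populations, points being single arrays (grey unsilenced, red silenced) and lines group means of n = 2. Parental cells moved from 4.76 to 9.73 for CEACAM5, and CD166-CD44- cells from 5.41 to 5.39.

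Adhesion genes (8 measured, 3 rose, 5 over the list alone, adjusted p = 2.04e-10) and retinoic acid genes (10 measured, 2 rose, 4 over the list alone, 2.84e-05) were higher, and their adjusted p with an estimated correlation was 0.00861 for each. Among retinoic acid genes STRA6, the retinol transporter, rose by 1.21 and HOXB4 by 0.75. Mitotic G2/M genes were higher (24 measured, median 0.54, adjusted p = 5.84e-12, and 0.262 with an estimated correlation), with PLK1 (0.84) and MKI67 (0.97) called over all genes and 13 over the list alone. NF-kB genes were higher (0.00673, and 0.279 with an estimated correlation), with the chemokine CXCL5 (1.25) called over all genes and over the list alone. Lists that were lower were p53 targets (TP53INP1 -1.01, 1 fell, 5 over the list alone, 5.22e-05), ribosome biogenesis (RRN3 -0.80, 1 fell, 4 over the list alone, 5.22e-05), NRF2 targets (2 fell, HMOX1 (-1.29) and SRXN1 (-0.80), 1 rose and 3 fell over the list alone, 0.0456) and cytosolic ribosomal proteins (median -0.12, no member called over either, 0.0337). With an estimated correlation the adjusted p of these 4 lists was 0.074 to 0.48. The NRF2 and ribosomal protein lists missed the threshold after quantile normalization (0.0683 and 0.0524) and cyclic loess (0.0792 and 0.0785). List calls lost with 1 array left out were NRF2 (0.0959 without silenced replicate 1 and 0.18 without unsilenced replicate 2), ribosomal protein (0.144 without silenced replicate 2 and 0.232 without unsilenced replicate 2) and NF-kB (0.0702 without silenced replicate 2).

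Leaving out 1 array gave 67 and 96 without unsilenced replicates 1 and 2, and 51 without silenced replicate 2, against 263. The 4 parental arrays fitted alone gave 30, without TSPAN7 (adjusted p = 0.0599). The list members named above other than CEACAM5 and CEACAM6 each lost the call without at least 1 array (adjusted p = 0.0507 to 0.353).

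In CD166+EpCAM+ cells silencing raised 93 genes and lowered 113. PLEK2, a pleckstrin of the actin cytoskeleton, rose by 2.23 ± 0.19 (adjusted p = 7.09e-06), from a level of 2.77 ± 0.13 (SD, n = 2 arrays) in unsilenced cells, followed by TRIML2 (1.71 ± 0.20) and EMP1 (1.43 ± 0.18). The RNA binding protein gene A1CF fell by 2.54 ± 0.21 (adjusted p = 7.09e-06), neurotensin (NTS) changed by -2.28 ± 0.32 and the neuropeptide Y receptor gene NPY1R by -2.28 ± 0.29 (adjusted p = 0.00103 and 0.000409). Retinoic acid genes were lower (10 measured, 1 fell, 5 over the list alone, adjusted p = 0.00114, and 0.0562 with an estimated correlation), the retinoid responder RARRES1 at -1.21. Mesenchymal genes were higher (11 measured, 1 rose, 2 over the list alone, 0.0272, and 0.18 with an estimated correlation), with the receptor tyrosine kinase AXL at 1.11 ± 0.16. G2/M genes were lower (24 measured, median -0.49, 1 fell, 13 over the list alone, 2.18e-13, and 0.26 with an estimated correlation), opposite in sign to parental cells, with NDC80 at -0.95. Lists without a called member over all genes were p53 targets, higher (0.0333, 5 higher and 1 lower over the list alone), ribosome biogenesis, higher (median 0.19, 0.0272), and oxidative phosphorylation, lower (median -0.20, 0.00241, 1 lower over the list alone), adjusted p = 0.26 to 0.502 with an estimated correlation. Small nucleolar RNAs, a sign of RNA preparation, were lower with them (median -0.25, 0.0333, and 0.657 with an estimated correlation).

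The p53 list missed the threshold after quantile normalization (0.0518). Leaving out an array ended the list calls of small nucleolar RNA (0.645) without unsilenced replicate 1 and mesenchymal (0.132), p53 (0.158) and ribosome biogenesis (0.102) without unsilenced replicate 2. Further list calls ended were p53 (0.182), ribosome biogenesis (0.513) and small nucleolar RNA (0.231) without silenced replicate 1 and mesenchymal (0.0599) without silenced replicate 2. With the labels of the silenced arrays exchanged within the EpCAM sort 190 genes were higher and 386 lower, A1CF (-1.58) and NPY1R (-2.23) kept their calls and the other 4 genes named did not, NTS turning to 1.55. Of the 7 lists only G2/M (median -0.51) and oxidative phosphorylation (-0.30) kept their calls, and ribosome biogenesis turned (-0.12, 0.0131), as did RARRES1 (1.28, 0.0174) and AXL (-0.60, 0.0407). The 93 higher and 113 lower genes became 80 higher and 156 lower after cyclic loess and 145 higher and 308 lower over every probe set, but 181 higher and 165 lower over genes above the median level. With 1 array left out the total was 48 and 72 without unsilenced replicates 1 and 2, 48 and 79 without silenced replicates 1 and 2. The 4 arrays fitted alone gave 91. RARRES1 lost its call without any 1 array (adjusted p = 0.243 and 0.151 without unsilenced replicates 1 and 2, 0.174 and 0.156 without silenced replicates 1 and 2), as did NDC80 (0.193 and 0.155 without unsilenced replicates 1 and 2, 0.0583 and 0.228 without silenced replicates 1 and 2).

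In CD166-EpCAM- cells 203 genes rose and 739 fell. VCAN fell by 2.99 ± 0.21 (adjusted p = 5.3e-07, n = 2 against 2 arrays), the thrombin receptor family gene F2RL2 changed by -1.88 ± 0.20 and the doublecortin family gene DCDC2 by -1.71 ± 0.21 (adjusted p = 0.000101 and 0.000274). The matrix gene EDIL3 (1.90 ± 0.24), the cytokine IL11 (1.61 ± 0.23) and FCGBP (1.34 ± 0.21) rose (adjusted p = 0.000305, 0.000843 and 0.00159). In the replication list 19 of 24 G1/S genes fell over all genes and 24 over the list alone, with a median of -0.86 (adjusted p = 3.23e-21, and 0.0821 with an estimated correlation), TYMS at -1.37 ± 0.16, MCM6 at -1.32 ± 0.17 and CDC6 at -1.20 ± 0.18. Of 24 G2/M genes 13 fell and 21 over the list alone (median -0.69, 3.18e-13), and of 25 ribosomal proteins 10 fell and 17 over the list alone (median -0.42, 3.51e-09), with RPL12 at -0.91. Of 21 ribosome biogenesis genes 4 fell, 10 over the list alone (median -0.34, 9.33e-06), and these 3 lists had an adjusted p of 0.0851 to 0.106 with an estimated correlation.

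Mesenchymal genes were lower in these cells (3 fell, 6 over the list alone, adjusted p = 0.0045, and 0.0851 with an estimated correlation), with AXL at -1.50 ± 0.16. Also lower were p53 targets (5 fell, 7 over the list alone, 0.000535, median -0.41), NRF2 targets (2 fell, 4 over the list alone, 0.00157, SRXN1 at -0.86), and unfolded protein response targets (5 fell, 2 rose and 6 fell over the list alone, 0.0259), with the serine synthesis genes PHGDH (-1.18) and PSAT1 (-1.15). With an estimated correlation the adjusted p of these 3 was 0.0868 to 0.231. Wnt genes (4 fell, 7 over the list alone, 0.0123) included the secreted Wnt inhibitor DKK1 at -1.40 ± 0.20, and the 12 Hedgehog genes (1 fell, over all genes and over the list alone, 0.0408) the transcription factor GLI1 at -1.07 ± 0.18, adjusted p = 0.106 to 0.147 with an estimated correlation. Hypoxia genes were lower (3 fell, 5 over the list alone, 0.0309) and adhesion genes higher (2 rose, over all genes and over the list alone, 0.0488). Their adjusted p with an estimated correlation was 0.176 to 0.228. Leukocyte markers moved up with these groups (6 measured, median 0.30, 0.0408, and 0.106 with an estimated correlation, none called over all genes and 1 over the list alone), with CD68 at 0.55 ± 0.17 (adjusted p = 0.0539), and so did the fall of the change with a gene's level (r across genes -0.31).

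The calls became 309 higher and 406 lower after quantile normalization and 299 higher and 318 lower after cyclic loess, which ended the list calls of Wnt (0.0659 and 0.111), unfolded protein response (0.114 and 0.179), hypoxia (0.114 and 0.223), leukocytes (0.072 and 0.0954) and, after loess, NRF2 (0.179). Left out, single arrays ended the list calls of Hedgehog (0.149), adhesion (0.0957), hypoxia (0.0559) and leukocyte (0.147) without unsilenced replicate 1 and adhesion (0.0637) and unfolded protein response (0.136) without unsilenced replicate 2. Silenced arrays left out ended hypoxia (0.0762) and leukocyte (0.148) without silenced replicate 1 and Hedgehog (0.202), adhesion (0.119) and unfolded protein response (0.09) without silenced replicate 2. After the exchange of labels 27 genes were higher and 52 lower, and VCAN (-1.33) and DCDC2 (-1.25) kept their calls while the other 4 genes named by size did not. Of the 13 lists G1/S (median -0.26, 0.00119, with 0 members called over all genes), G2/M (-0.69), Wnt (-0.17) and adhesion genes (0.09) kept theirs, the other 9 lost them (0.289 to 0.98), and of the called members named only DKK1 (-0.93) stayed, with TYMS at -0.66 and AXL at 0.21. Totals with 1 array left out were 156 and 307 without unsilenced replicates 1 and 2, and 245 without silenced replicate 1, against 942. The 4 arrays fitted alone gave 44, without EDIL3 (0.0563), GLI1 (0.0557), SRXN1 (0.0628) and RPL12 (0.0561).

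In CD166+CD44+ cells 269 genes rose and 685 fell. NID2 rose by 1.86 ± 0.20 (adjusted p = 0.000139), CEACAM7 by 1.54 ± 0.30 and the proteoglycan lumican (LUM), one of the stromal markers fixed, by 1.51 ± 0.19 (adjusted p = 0.00917 and 0.000485, n = 2 against 2 arrays). ULBP1, a ligand of the natural killer cell receptor NKG2D, changed by -2.56 ± 0.49, A1CF by -2.02 ± 0.21 and the ankyrin repeat gene ANKRD1 by -1.90 ± 0.27 (adjusted p = 0.00847, 0.000139 and 0.00129). Mesenchymal genes were lower (1 rose and 4 fell, 1 and 7 over the list alone, adjusted p = 0.00469, and 0.168 with an estimated correlation), with fibronectin (FN1) at -1.24 ± 0.17 and AXL at -1.25 ± 0.16. Of 17 unfolded protein response targets 6 fell (1 rose and 8 fell over the list alone, 0.00469), with VLDLR (-1.30) and PSAT1 (-1.27). Of 21 ribosome biogenesis genes 5 fell (9 over the list alone, 6.02e-06), with NOC3L at -1.02 ± 0.18, and these 2 lists had an adjusted p of 0.212 to 0.219 with an estimated correlation. Adhesion genes were higher (0.0244, and 0.219 with an estimated correlation), CEACAM5 and CEACAM6 rising by 1.44 and 0.93, the 2 called over all genes and over the list alone.

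Lower in the same cells were G2/M genes (median -0.39, 2 fell, 7 over the list alone, adjusted p = 1.21e-05), G1/S genes (median -0.31, 3 fell, 3 over the list alone, 0.0023), p53 targets (4 fell, 5 over the list alone, 0.00263, median -0.44) and hypoxia genes (3 fell, 5 over the list alone, 0.0113, median -0.28). The 4 lists had an adjusted p of 0.212 to 0.363 with an estimated correlation. Cholesterol biosynthesis genes were higher with none called over either (median 0.23, 0.0222, and 0.219 with an estimated correlation). Small nucleolar RNAs, a sign of RNA preparation, and leukocyte markers moved with these groups. Small nucleolar RNAs passed as higher (1 rose and 1 fell, 6 rose and 1 fell over the list alone, median 0.23, 0.0276, and 0.556 with an estimated correlation), but 1 array stood apart. In silenced replicates 1 and 2 SCARNA3 was at 4.20 and 6.75, SCARNA7 at 7.24 and 8.83 and SCARNA16 at 6.33 and 7.96, and without replicate 2 the list was lower with a median of -0.08 (adjusted p = 0.578). Leukocyte markers were higher (1 rose over all genes and over the list alone, 0.0386, and 0.212 with an estimated correlation), CD68 at 0.76 ± 0.17 (adjusted p = 0.015, but 0.0815 and 0.117 without unsilenced replicates 1 and 2, and 0.106 without silenced replicate 2). The change fell with a gene's level (r across genes -0.36).

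The calls became 227 higher and 261 lower after quantile normalization and 209 higher and 257 lower after cyclic loess, which ended the list calls of G1/S (0.11 and 0.139), hypoxia (0.0552 and 0.0888) and leukocytes (0.0851 and 0.0771). Leaving out 1 unsilenced array ended the list calls of adhesion (0.115), cholesterol (0.0983) and hypoxia (0.0796) without unsilenced replicate 1 and leukocyte (0.0741) and small nucleolar RNA (0.0675) without unsilenced replicate 2. Leaving out 1 silenced array ended adhesion (0.151), cholesterol (0.174) and leukocyte (0.068) without silenced replicate 1 and leukocyte (0.0909) and small nucleolar RNA (0.578) without silenced replicate 2. Leaving out 1 array gave 110 and 80 without unsilenced replicates 1 and 2, and 199 without silenced replicate 2, against 954. The adjusted p of CEACAM7 was 0.103 without unsilenced replicate 2 and 0.0713 without silenced replicate 2 and that of ULBP1 0.0898 without unsilenced replicate 1 and 0.0857 without silenced replicate 2. The 4 arrays fitted alone gave 16, without LUM and ULBP1 (0.0746 each), FN1 (0.0523), AXL (0.0551), PSAT1 (0.0706), NOC3L (0.102) and CEACAM6 (0.0747).

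In CD166-CD44- cells 193 genes rose and 344 fell. SNAI2, a transcription factor of the epithelial to mesenchymal transition, rose by 1.55 ± 0.17 (adjusted p = 0.000149), CCBE1 by 1.41 ± 0.20 and the neurotrophic factor receptor gene GFRA1 by 1.38 ± 0.23 (adjusted p = 0.000911 and 0.00353, n = 2 against 2 arrays). The sperm calcium channel subunit gene CATSPERB changed by -2.35 ± 0.27, TMEM47 by -1.92 ± 0.20 and CCDC68 by -1.76 ± 0.24 (adjusted p = 0.000171, 0.000133 and 0.00079). Mesenchymal genes passed as higher (4 rose and 1 fell, over all genes and over the list alone, adjusted p = 0.0262), with SNAI1 at 1.33 ± 0.14, AXL at 0.95 and FN1 at -0.91, although the list's median was -0.04 while its mean was 0.32, an adjusted p of 0.283 with an estimated correlation. G1/S genes were higher, opposite in sign to CD166-EpCAM- and CD166+CD44+ cells (4 rose, 14 over the list alone, median 0.45, 2.12e-08, and 0.374 with an estimated correlation), with the replication licensing factor CDT1 at 0.85. The p53 targets were higher (1 rose, 3 over the list alone, 0.0262), the apoptosis gene BAX at 1.10, and ribosomal proteins were higher with none called over either (median 0.14, 0.0262), adjusted p = 0.374 to 0.648 with an estimated correlation.

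Among lists the ribosomal protein (0.0506 and 0.0881 without silenced replicates 1 and 2, and 0.119 without unsilenced replicate 2), p53 (0.231 without silenced replicate 1 and 0.119 without unsilenced replicate 2) and mesenchymal calls (0.147 without silenced replicate 1) were lost with 1 array left out. Totals with 1 array left out were 181 and 170 without unsilenced replicates 1 and 2, 918 and 43 without silenced replicates 1 and 2, against 537. Without unsilenced replicate 1 the excess of lower genes was gone, with 99 higher and 82 lower. The adjusted p of GFRA1 was 0.0824 without silenced replicate 2. For AXL it was 0.0534 without unsilenced replicate 2 and 0.0824 without silenced replicate 2, for FN1 0.0824 without silenced replicate 2, for BAX 0.0755 without silenced replicate 2 and for CDT1 0.156 without unsilenced replicate 1 and 0.252 without silenced replicate 2. The 4 arrays fitted alone gave 118.

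An F test found 1668 genes with different silencing effects among the 5 populations. Of 2342 genes called in at least 1 population, 438 were called in more than 1, and 208 of these were higher in some and lower in others, while none was called in one direction in all 5. PIEZO2 and TSPAN7 were lower in 4, and so was UPK1B, a further tetraspanin gene, named after its values were seen, which was higher in parental cells, but none of these 3 kept its call in CD166-EpCAM- cells with the labels of the silenced arrays exchanged within the EpCAM sort. With that exchange the counts of 1668, 2342, 438 and 208 became 1165, 2029, 302 and 142. CD166-EpCAM- and CD166+CD44+ cells, a non-stem and a stem population, had the highest correlation (r across genes 0.37), with 155 genes lower in both against 34.0 by chance overlap and 12 higher in both against 3.67. These are the populations whose changes fell with a gene's level. After quantile normalization and cyclic loess their r was 0.27 and 0.27, still the highest of the 10 pairs, with 54 and 47 genes lower in both. After the exchange it was 0.12, with 8 lower in both, and the highest was that of parental and CD166+EpCAM+ cells. CD166+EpCAM+ and CD166-CD44- cells shared 31 lower and 12 higher genes against 2.61 and 1.21 (r = 0.21), but 16 and 2 after the exchange, with 40 opposite (r = -0.06). Within each sort opposite and shared lower calls both exceeded chance overlap. As that baseline and Fisher's test take genes as equally easy to call, this excess alone shows no common response. Between CD166+EpCAM+ and CD166-EpCAM- cells (r = -0.13) 39 genes were opposite against 6.16 and 14 lower in both against 5.61 (one-sided Fisher's exact test, p = 0.0014, adjusted p = 0.00234), and after the exchange 14 against 1.36 and 10 against 1.35 (r = -0.00123). Between CD166+CD44+ and CD166-CD44- cells (r = 0.07) 57 were opposite against 15.1 and 26 lower in both against 15.8 (p = 0.00914, adjusted p = 0.0131 over 10 pairs). Changes in parental cells correlated with those in CD166+CD44+ (r = 0.14) and CD166-CD44- cells (r = -0.11), and with those in CD166-EpCAM- (r = 0.22) and CD166+EpCAM+ cells (r = -0.17), where the exchange turned both signs (r = -0.15 and 0.20). These populations shared no arrays, and genes are not independent replicates.

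**Figure D3:**
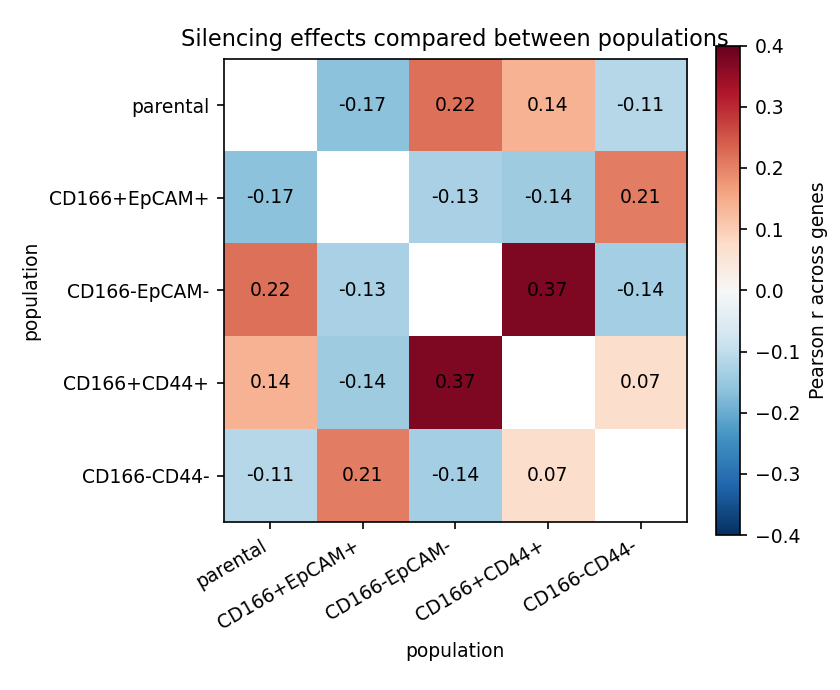
Pearson correlation across 14884 genes (colour and printed value) between the silencing effects of each pair of the 5 populations, on both axes. The highest value, 0.37, joins CD166-EpCAM- and CD166+CD44+ cells, and the lowest, -0.17, parental and CD166+EpCAM+ cells.

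**Figure D4:**
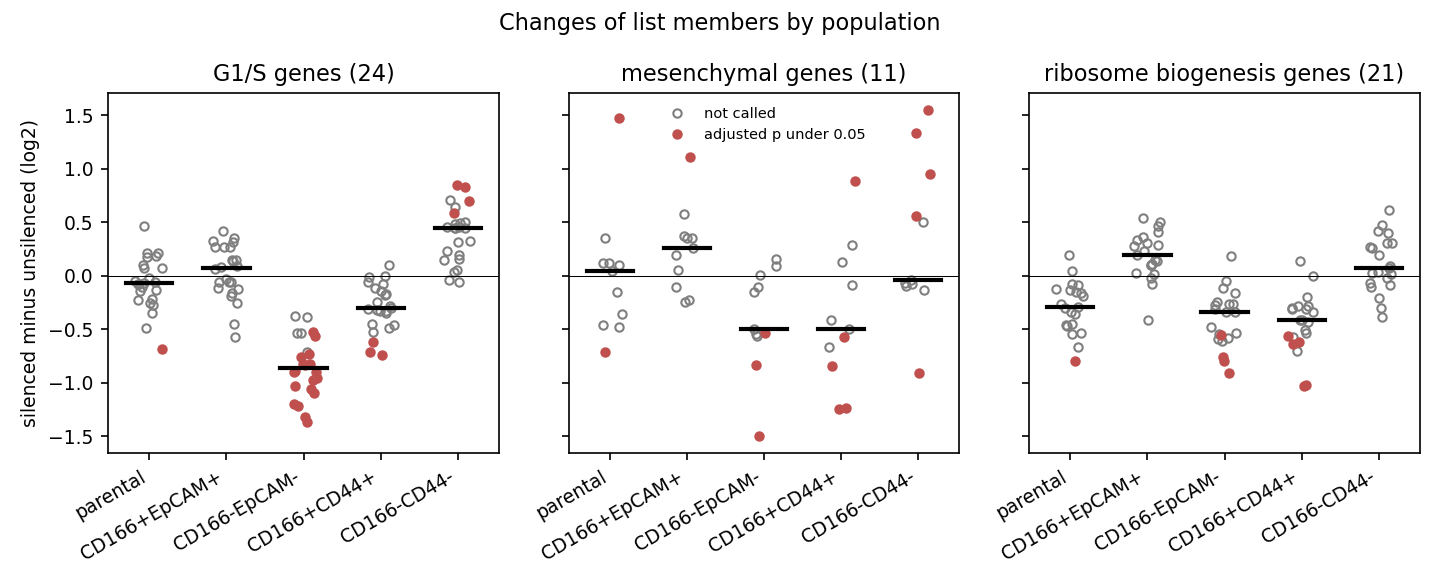
Log2 change by silencing (vertical axis) of each measured member of the G1/S (24 genes), mesenchymal (11) and ribosome biogenesis lists (21) in the 5 populations, filled red where the adjusted p was under 0.05, with a black bar at the median. G1/S medians lay at -0.86 in CD166-EpCAM- and 0.45 in CD166-CD44- cells.

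Without silencing, stem and non-stem cells differed in 193 genes in the mean of both sorts, 60 higher and 133 lower in stem cells. CEACAM5 was higher by 3.09 ± 0.14 (adjusted p = 4.91e-10, n = 4 against 4 arrays), A1CF by 1.87 ± 0.15 (adjusted p = 2.59e-06) and TSPAN7 by 1.40 ± 0.15 (adjusted p = 8.06e-05). Further genes higher in stem cells of both sorts were MAPK4 (1.25), NPY1R (1.20), SYT13 (0.99), SGPP2 (0.98), BMP2 (0.96), BAAT (0.89) and CEACAM6 (0.85). Lower were the ephrin receptor EPHA5 (-1.49 ± 0.13, adjusted p = 8.34e-06) and the Hedgehog pathway transcription factor GLI1 (-1.05 ± 0.13, adjusted p = 0.000322), with TRIML2 (-1.16), ZNF420 (-1.04), PCDHB5 (-1.01), DNAAF11 (-0.99), ANKRD29 (-0.99), OLFML2A (-0.99), DRD1 (-0.97) and BMPER (-0.96). Adhesion genes were higher (2 of 8 higher, 5 over the list alone, adjusted p = 1.15e-05), oxidative phosphorylation genes were higher with 1 member over the list alone (median 0.22, 0.000214), and p53 targets were lower (2 lower, 3 over the list alone, 0.000666), with TP53INP1 at -0.76 ± 0.12. With an estimated correlation the adjusted p of these 3 lists was 0.109 to 0.164. Hypoxia genes were higher (1 higher, 3 over the list alone, 0.0203), as were NRF2 targets without a called member (median 0.03, 0.0485), and NF-kB genes were lower without one (median -0.29, 0.0203), adjusted p = 0.215 to 0.324 with an estimated correlation. The list of stem cell genes did not pass (adjusted p = 0.878).

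Of the lists, NRF2 lost its call (without any 1 of 6 arrays, 0.0539 to 0.112). Hypoxia (0.0863 without unsilenced CD166+CD44+ replicate 1) and NF-kB (0.066 without unsilenced CD166-CD44- replicate 1) lost theirs once each. The 60 higher and 133 lower genes became 75 higher and 84 lower after quantile normalization and 77 higher and 97 lower after cyclic loess. Leaving out 1 array gave 68 and 99 without unsilenced CD166+EpCAM+ replicates 1 and 2, 69 and 117 without unsilenced CD166-EpCAM- replicates 1 and 2. Further totals were 85 and 75 without unsilenced CD166+CD44+ replicates 1 and 2, 83 and 110 without unsilenced CD166-CD44- replicates 1 and 2. BAAT lost its call without any 1 of 5 arrays (adjusted p = 0.0504 to 0.0626) and ANKRD29 without either of 2 (0.0524 to 0.0575).

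In the EpCAM sort alone 38 genes were higher and 63 lower in stem cells. CEACAM5 (1.61 ± 0.20), the cytokine IL33 (1.61 ± 0.18) and ALG1L2 (1.5 ± 0.29) were higher (adjusted p = 0.000756, 0.000535 and 0.0228, n = 2 against 2 arrays), and PLEK2 (-1.75 ± 0.19), TRIML2 (-1.46 ± 0.20) and F2RL2 (-1.46 ± 0.20) lower (adjusted p = 0.000535, 0.00179 and 0.00198). Adhesion genes were higher (2 over all genes and over the list alone, adjusted p = 0.0123, and 0.474 with an estimated correlation), with CEACAM6 at 1.29 ± 0.15. Oxidative phosphorylation genes were higher (median 0.16, 0.0123) and G1/S (median -0.29, 0.0022) and ribosome biogenesis genes (median -0.20, 0.0194) lower, each with no member called over either, and adjusted p = 0.481 to 0.724 with an estimated correlation. The p53 targets were lower (1 over all genes, 2 over the list alone, 0.0359, and 0.481 with an estimated correlation). The p53 and ribosome biogenesis lists missed the threshold after quantile normalization (0.081 and 0.0911) and loess (0.0872 and 0.0971). Leaving out an array also ended the list calls of oxidative phosphorylation (0.0617) without unsilenced CD166+EpCAM+ replicate 1 and G1/S (0.0808), p53 (0.205) and ribosome biogenesis (0.118) without unsilenced CD166+EpCAM+ replicate 2. Others ended were oxidative phosphorylation (0.0862) without unsilenced CD166-EpCAM- replicate 1 and p53 (0.348) and ribosome biogenesis (0.0841) without unsilenced CD166-EpCAM- replicate 2. The split became 49 higher and 49 lower after quantile normalization and 48 higher and 47 lower after loess. With 1 array left out the total was 18 and 39 without unsilenced CD166+EpCAM+ replicates 1 and 2, 17 and 26 without unsilenced CD166-EpCAM- replicates 1 and 2. The excess of lower genes turned over every probe set, named or not, with 169 higher and 86 lower. It also turned without unsilenced CD166+EpCAM+ replicate 2 (24 and 15), without unsilenced CD166-EpCAM- replicates 1 (9 and 8) and 2 (14 and 12) and with a 2-fold change required (22 and 17). The adjusted p of ALG1L2 was 0.0877 and 0.205 without unsilenced CD166+EpCAM+ replicates 1 and 2, 0.166 and 0.109 without unsilenced CD166-EpCAM- replicates 1 and 2. With the 4 arrays alone limma called 0 (2095 at an unadjusted p under 0.05, adjusted p = 0.0564 for each gene named).

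In the CD44 sort 79 genes were higher and 142 lower in stem cells. CEACAM5 was higher by 4.56 ± 0.20 (adjusted p = 2.31e-10), 9.97 against 5.41 (n = 2 arrays each), A1CF by 2.56 ± 0.21 and TSPAN7 by 1.79 ± 0.21 (adjusted p = 4.23e-06 and 0.000283). EPHA5 (-2.20 ± 0.19), ZNF420 (-1.61 ± 0.23) and EFEMP1 (-1.29 ± 0.15) were lower (adjusted p = 4.23e-06, 0.00207 and 0.000193). G1/S genes were higher (1 over all genes, 4 over the list alone, median 0.35, adjusted p = 3.23e-09), G2/M genes were higher (2, 5 over the list alone, 0.0016), and so were adhesion genes (1, 5 over the list alone, 4.2e-05), hypoxia genes (0, 4 over the list alone, 0.0016) and oxidative phosphorylation genes (0, 1 over the list alone, 0.00719). With an estimated correlation the adjusted p of these 5 lists was 0.133 to 0.495. Lower were p53 targets (2, 3 over the list alone, 0.00719), interferon-stimulated genes (1, 5 over the list alone, 0.0261) and NF-kB genes (0, 4 over the list alone, 0.0117), adjusted p = 0.133 to 0.259 with an estimated correlation. The list calls ended by leaving out an array were interferon (0.147) without unsilenced CD166+CD44+ replicate 1, G1/S (0.0539), G2/M (0.771), NF-kB (0.118) and p53 (0.0858) without unsilenced CD166-CD44- replicate 1 and interferon (0.146) and oxidative phosphorylation (0.0705) without unsilenced CD166-CD44- replicate 2. The split became 103 higher and 106 lower after median centring. Totals with 1 array left out were 29 and 20 without unsilenced CD166+CD44+ replicates 1 and 2, 49 and 86 without unsilenced CD166-CD44- replicates 1 and 2. Higher genes were in excess without unsilenced CD166+CD44+ replicate 1 (15 and 14) and unsilenced CD166-CD44- replicate 1 (27 and 22). The adjusted p of ZNF420 was 0.0677 without unsilenced CD166+CD44+ replicate 2. The 4 arrays fitted alone gave 5, without ZNF420 (0.0875) and EFEMP1 (0.0653).

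The sorts had 15 genes differing in the same direction, against 0.803 by chance overlap, and 6 in opposite directions, against 0.697, with r = 0.07 across genes. Shared and higher in stem cells were A1CF, BMP2, CEACAM5, MAPK4, SYT13 and TSPAN7, and shared and lower were CA8, DNAAF11, DRD1, GLI1, MMD, PDGFRL, POGLUT2, TP53INP1 and TRIML2. AXL was among the 6 opposite genes.

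The silencing effect differed between stem and non-stem cells of the EpCAM sort in 865 genes, 642 changing upward and 223 downward in CD166+EpCAM+ relative to CD166-EpCAM- cells. PLEK2 rose by 2.23 in stem and changed by -1.57 in non-stem cells, a difference of 3.80 ± 0.27 (adjusted p = 6.99e-07, n = 2 arrays in each of 4 groups). TRIML2 (2.98 ± 0.28) and F2RL2 (2.96 ± 0.29) followed, and the complement factor I gene CFI (-3.35 ± 0.38), NTS (-2.83 ± 0.45) and ALG1L2 (-2.50 ± 0.42) differed the other way (adjusted p = 8.38e-05, 0.00169 and 0.00227). G1/S genes moved upward in stem relative to non-stem cells (12 of 24 over all genes, 16 over the list alone, median 0.85, adjusted p = 3.33e-13, and 0.0874 with an estimated correlation), with DTL (1.52), CDC6 (1.55) and UNG (1.22). The same held for ribosome biogenesis (4, 13 over the list alone, median 0.61, 3.53e-06), p53 targets (6, 6 over the list alone, 0.000435, BAX at 1.55 and SESN2 at 2.25), mesenchymal genes (3, 4 over the list alone, 0.000731, AXL at 2.61 ± 0.22) and ribosomal proteins (1, 6 over the list alone, 0.0012). These 4 lists had an adjusted p of 0.059 to 0.337 with an estimated correlation. Retinoic acid genes moved downward (1, 3 over the list alone, 0.00213, RARRES1 at -2.38 ± 0.40), as did the small nucleolar RNAs (1 over all genes and over the list alone, 0.0435), adjusted p = 0.059 to 0.566 with an estimated correlation.

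The calls of ribosomal proteins after loess (0.0947) and of small nucleolar RNAs after median centring (0.0602) were lost. The latter list also missed the threshold without any 1 of 4 arrays, 0.0866 to 0.283. The calls became 317 higher and 297 lower after quantile normalization and 262 higher and 305 lower after cyclic loess. With 1 array left out the total was 449 and 385 without unsilenced CD166+EpCAM+ replicates 1 and 2, 354 without silenced CD166+EpCAM+ replicate 1, 365 and 491 without unsilenced CD166-EpCAM- replicates 1 and 2, and 419 without silenced CD166-EpCAM- replicate 1. The 8 arrays fitted alone gave 536. After the exchange of labels 205 genes were called, 101 higher and 104 lower, and 0 of the 6 genes named by size kept the call, with PLEK2 at -0.31 and NTS at 4.84. None of the 7 lists kept its call. G1/S genes (median -0.48, 9.43e-05), ribosomal proteins (-0.59, 7.08e-08) and retinoic acid genes (0.37, 0.00153) passed in the other direction, the 4 others missed the threshold (0.0801 to 0.976), and AXL was at -0.81 (adjusted p = 0.0789) and RARRES1 at 2.60 (0.00211).

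In the CD44 sort the silencing effect differed in 493 genes, 182 upward and 311 downward in CD166+CD44+ relative to CD166-CD44- cells. CATSPERB (3.20 ± 0.39), the cornified envelope gene SCEL (2.70 ± 0.26) and AGR2 (2.52 ± 0.22), a protein disulfide isomerase of secretory cells, differed upward (adjusted p = 0.000177, 2.74e-05 and 1.91e-05), and A1CF (-2.43 ± 0.30), GFRA1 (-2.43 ± 0.33) and KLHL4 (-2.37 ± 0.28) downward (adjusted p = 0.000208, 0.000442 and 0.000177, n = 2 arrays in each of 4 groups). Mesenchymal genes moved downward in stem relative to non-stem cells (4 of 11 over all genes, 1 upward and 6 downward over the list alone, median -0.76, adjusted p = 2.24e-05, and 0.0182 with an estimated correlation), with AXL (-2.19), SNAI1 (-1.75), SNAI2 (-1.42) and VIM (-1.13), where 2 further VIM probe sets gave -0.75 and -0.95. Also downward were G1/S (5, 15 over the list alone, 1.22e-10, MCM5 at -1.31) and G2/M genes (4, 7 over the list alone, 2.31e-06, CDC20 at -1.65), p53 targets (3, 6 over the list alone, 1.22e-05, BAX at -1.53), hypoxia genes (1, 3 over the list alone, 0.00141, ADM at -1.32), ribosome biogenesis (0, 10 over the list alone, 7.24e-07) and ribosomal proteins (0 over either, 0.00649). These 6 lists had an adjusted p of 0.0718 to 0.319 with an estimated correlation. Adhesion genes moved upward (2, 3 over the list alone, 0.00614, CEACAM6 (2.34) and CEACAM5 (1.45)), as did retinoic acid genes (1, 2 over the list alone, 0.041, RDH10 at 2.11), adjusted p = 0.121 to 0.144 with an estimated correlation. Leukocyte markers moved upward with them (median 0.53, 0 over either, 0.041, and 0.121 with an estimated correlation).

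The calls of ribosomal proteins (0.15 and 0.152) and leukocytes (0.0689 and 0.0588) were lost after quantile normalization and loess. Ribosomal proteins lost their list call at 0.176 without silenced CD166+CD44+ replicate 1, retinoic acid genes theirs without any 1 of 4 arrays, 0.0536 to 0.115, and leukocyte markers without any 1 of 4 arrays, 0.0697 to 0.096. The calls became 223 higher and 209 lower after quantile normalization and 219 higher and 217 lower after cyclic loess. Leaving out 1 array gave 255 and 212 without unsilenced CD166+CD44+ replicates 1 and 2, 297 without unsilenced CD166-CD44- replicate 2 and 238 without silenced CD166-CD44- replicate 2. The 8 arrays fitted alone gave 229. Across genes the interactions of the sorts correlated with r = -0.43, with 162 genes called in both in opposite directions against 16.1 by chance overlap, and 1, A1CF, in the same direction against 12.5. After the exchange of silenced labels in the EpCAM sort r was 0.12, and after one in the CD44 sort 0.31.

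In the mean of both sorts 36 genes responded differently in stem and non-stem cells, 27 upward and 9 downward. A1CF moved downward in stem relative to non-stem cells of both sorts, by -2.28 ± 0.21 (adjusted p = 5.3e-05, n = 2 arrays in each of 8 groups), and the myosin gene MYO1D moved upward by 1.40 ± 0.15 (adjusted p = 0.000245). The other genes named by size were TSPAN1 (1.23), MATN3 (1.14), PARM1 (1.12), ANKRD30A (1.10), TMEM47 (1.10), TSPAN13 (1.05), PAX7 (1.02), LCN2 (0.98) and SPDYE4 (0.98) upward, and TFR2 (-0.91), CSF1 (-0.74), CHML (-0.73) and URB1 (-0.64) downward. Calls of these 13 genes depended on single arrays, those of A1CF and MYO1D did not. A1CF in unsilenced CD166-CD44- cells was already low (2.79 and 2.62, CD166+CD44+ 5.19 and 5.34), with less room to fall. Of the lists, G2/M genes passed as lower (median -0.20, no member called over all genes or over the list alone, adjusted p = 0.00324, and 0.928 with an estimated correlation). That call was lost at 0.228 without unsilenced CD166-CD44- replicate 1 and 0.0559 without silenced CD166-EpCAM- replicate 2. With the silenced labels of the EpCAM sort exchanged 217 genes were higher and 355 lower. A1CF was then at -1.32 in the mean and -0.22 in that sort, and 6 of the 15 genes named kept their call, MYO1D (0.34, adjusted p = 0.224) not among them, as did the G2/M list (-0.20, 0.0134). The split became 25 higher and 14 lower after quantile normalization, and leaving out 1 array gave 3 to 17 genes, except 27 without silenced CD166-EpCAM- replicate 2, and 38 and 24 without silenced CD166+CD44+ replicates 1 and 2.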

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

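Apart from the excess of lower genes and the rise of CEACAM5, the results in this part are silencing effects that differed between groups by a test of the difference itself. Counts of other splits were set beforehand. Tests of exchanged labels, scaling, growth state, compression, shared probes, wrong labels and a common effect were chosen only after the result was seen.

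Stem minus non-stem interactions of the sorts ran in opposite directions (865 genes in the EpCAM and 493 in the CD44 sort, r = -0.43 across genes). Of 221 genes separating unsilenced CD166+CD44+ from CD166-CD44- cells, 69.2% kept their sign between silenced arrays (exact 95% interval 62.7 to 75.25). That leans against exchanged labels in the CD44 sort, though such intervals take genes as independent and may be too narrow. After quantile normalization r remained -0.38, which argues against level-dependent scaling. In the EpCAM sort the share was 35.6% of 101 (26.4 to 45.8), as exchanged labels of its silenced arrays could give, and exchanging them turned the 865 genes into 205, the silencing calls of 206 in stem and 942 in non-stem cells into 576 and 79, and r into 0.123. That r turns does not point to the EpCAM labels, since exchange in the CD44 sort turned it too (0.306), with 1492 genes in place of 493. Removal of G1/S and G2/M scores brought r to -0.00469, nearer to 0 than all but 2 of 100 random pairs of lists but within the 5 and 95 percentiles of those pairs (-0.259 to 0.110), so both outcomes set for that test were met and growth state cannot be told apart from other variation. A true difference in how the sorted populations responded stays open and was not tested.

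Of the 835 genes changed by silencing on average 667 were lower. Only the real one of 100 splits, drawn from 3888, called as many (812 at most in others). Other splits add silencing effects to the residual spread, so chance stays open. Compression of values on the 4 silenced arrays of CD166-EpCAM- and CD166+CD44+ cells cannot be told apart from a wider fall of abundant transcripts in these cells, since all 4 arrays and no unsilenced array of these populations lost signal with rising level (r of the deviation with level -0.286, -0.221, -0.149 and -0.242, against 0.00589 to 0.211). Compression forbids an excess of lower genes at levels under 4, where the median change was above 0, and there 48.6% of 146 called genes were higher (exact 95% interval 40.3 to 57.0), against 14.1% of 689 at other levels. Centring on medians left 23.5% of called genes higher, against 20.1% before, and over the other 3 populations 52.5% were higher. For the 12 lists that passed, 2 of 100 splits gave as many, the real one included, the other with 13, with the same limit. With an estimated correlation none of the 12 passed (adjusted p = 0.173 to 0.543).

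CEACAM5 rose by 4.97 in parental cells and not in each population. Probes shared with CEACAM6 are argued against by the gap between these genes, which ranged by 4.65 over the 10 groups with a pooled SD of 0.159. Correlation of unsilenced with silenced parental arrays (0.415, next group 0.0864) argues against a label from sorted cells, but holds under exchanged parental labels. One effect common to all populations is argued against for these arrays only. The 95% interval ended at -0.18 in CD166+EpCAM+ and 0.40 in CD166-CD44- cells, under the 4.55 to 5.39 of parental cells. A response of parental and CD166+CD44+ cells alone, exchanged parental labels or a difference between cultures stay open and untested.

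Silencing effects differed among the 5 populations in 1668 genes by the F test. In the EpCAM sort they differed between stem and non-stem cells for PLEK2 (3.80), TRIML2 (2.98) and F2RL2 (2.96) upward and CFI (-3.35), NTS (-2.83) and ALG1L2 (-2.50) downward. Lists with a tested difference there had medians of -0.39 for retinoic acid genes, 0.42 for mesenchymal genes, 0.85 for G1/S genes, 0.58 for p53 targets, 0.61 for ribosome biogenesis, 0.39 for ribosomal proteins and -0.19 for small nucleolar RNAs, but with an estimated correlation none of the 7 passed (adjusted p = 0.059 to 0.566) and with exchanged labels none kept its call, G1/S genes, ribosomal proteins and retinoic acid genes passing in the other direction. In the CD44 sort the genes were CATSPERB (3.20), SCEL (2.70) and AGR2 (2.52) upward and A1CF (-2.43), GFRA1 (-2.43) and KLHL4 (-2.37) downward. The list medians were 0.28 for retinoic acid genes, -0.76 for mesenchymal genes, -0.68 for G1/S and -0.53 for G2/M genes, -0.61 for p53 targets, -0.26 for hypoxia genes, -0.60 for ribosome biogenesis, -0.31 for ribosomal proteins, 0.40 for adhesion genes and 0.53 for leukocyte markers. With an estimated correlation only the mesenchymal list passed (adjusted p = 0.0182, against 0.0718 to 0.319 for the others), and those of ribosomal proteins and leukocytes were lost after quantile normalization and cyclic loess.

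In the mean of both sorts the interaction was called in 36 genes, named by size MYO1D (1.40), TSPAN1 (1.23), MATN3 (1.14), PARM1 (1.12), ANKRD30A (1.10), TMEM47 (1.10), TSPAN13 (1.05), PAX7 (1.02), LCN2 (0.98) and SPDYE4 (0.98) upward and A1CF (-2.28), TFR2 (-0.91), CSF1 (-0.74), CHML (-0.73) and URB1 (-0.64) downward, and in 1 list, G2/M genes at a median of -0.20. With the labels of the silenced arrays exchanged in the EpCAM sort 572 genes were called. For these counts chance cannot be excluded, as 5 of 100 splits drawn from 648 gave as many genes, with 714 the highest of the others, and 78 gave as many lists, with 13 the highest. Splits calling several times the real count point to a structure of the samples, of which the opposite interactions of the sorts, cancelling in the mean, may be a part, though this was not tested. For the mean stem difference without silencing the 18 splits are too few for a share under 0.05, with 193 genes against 75 in the highest other split, and 6 lists against 7.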

How the results depend on the processing

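Cyclic loess, the mean over 3 populations, the likeness of populations under other scalings and the retests of single lists without 1 array were chosen only after the result was seen. Centring on medians kept every count within 1.5 times the main one. Counts that moved further follow by setting, and except where fewer genes or arrays entered, or a change of 2-fold was required, the cause was not tested.

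Quantile normalization gave for silencing 489 (mean silencing) and 488 (CD166+CD44+). Cyclic loess gave for silencing 509 (mean silencing), 617 (CD166-EpCAM-) and 466 (CD166+CD44+) and for interactions 567 (the EpCAM sort). Over the 3 populations without CD166-EpCAM- and CD166+CD44+, mean silencing gave 261 genes and 3 lists. There 4 list members reversed, the cell cycle kinase gene BUB1 at 0.045, SESN2 at 0.018, ADM at 0.089 and RPL12 at 0.0060, none past the threshold. Genes above the median level gave for silencing 1335 (mean silencing), 346 (CD166+EpCAM+) and 822 (CD166-CD44-), for stem differences 172 (the EpCAM sort) and 344 (the CD44 sort) and for interactions 792 (the CD44 sort). Every probe set counted by itself gave for silencing 453 (CD166+EpCAM+), for stem differences 255 (the EpCAM sort) and for interactions 10 (the sorts' mean). With trend and robust, eBayes gave for stem differences 169 (the EpCAM sort). Array weights gave for silencing 505 (parental cells), 361 (CD166+EpCAM+), 540 (CD166+CD44+) and 325 (CD166-CD44-), for stem differences 238 (the EpCAM sort), 463 (the CD44 sort) and 400 (the sorts' mean) and for interactions 296 (the CD44 sort) and 23 (the sorts' mean). The arrays compared, fitted alone, gave for silencing 30 (parental cells), 91 (CD166+EpCAM+), 44 (CD166-EpCAM-), 16 (CD166+CD44+) and 118 (CD166-CD44-), for stem differences 0 (the EpCAM sort) and 5 (the CD44 sort) and for interactions 536 (the EpCAM sort) and 229 (the CD44 sort), where limma's 0 stands beside 2095 at an unadjusted p under 0.05. An adjusted p with a 2-fold change gave for silencing 5 (mean silencing), 83 (parental cells), 74 (CD166+EpCAM+), 127 (CD166-EpCAM-), 120 (CD166+CD44+) and 110 (CD166-CD44-), for stem differences 39 (the EpCAM sort), 56 (the CD44 sort) and 10 (the sorts' mean) and for interactions 471 (the EpCAM sort) and 14 (the sorts' mean). An unadjusted p with a 2-fold change gave for silencing 5 (mean silencing), 94 (parental cells), 86 (CD166+EpCAM+), 133 (CD166-EpCAM-), 134 (CD166+CD44+) and 119 (CD166-CD44-), for stem differences 60 (the EpCAM sort), 70 (the CD44 sort) and 10 (the sorts' mean) and for interactions 562 (the EpCAM sort).

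Of the lists, camera with an estimated correlation passed 0 for mean silencing, 0 for the mean stem difference and 0 for the mean interaction (5, 5 and 0 at an unadjusted p under 0.05), against 12, 6 and 1 with the preset one. The directional test of fry passed 16, 4 and 0 (16, 7 and 2 unadjusted), and 21, 11 and 8 lists had any member past the threshold over the list alone.

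Leaving out 1 array gave 377 to 1294 genes for mean silencing, and in parental, CD166+EpCAM+, CD166-EpCAM-, CD166+CD44+ and CD166-CD44- cells 51 to 316, 48 to 79, 156 to 653, 80 to 1406 and 43 to 918. Stem differences ranged over 17 to 39 in the EpCAM sort, 20 to 86 in the CD44 sort and 68 to 117 in their mean, and interactions over 354 to 718, 212 to 669 and 3 to 38. Lists numbered 10 to 12, 4 to 8 and 0 to 2 in the mean comparisons. With 1 array left out the small nucleolar RNA list in CD166+CD44+ cells had medians from -0.0797 to 0.548, reversed without silenced replicate 2. The array left alone in its group is assumed to vary like the others.

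The replicate numbers did not pair the arrays, as deviations of same-numbered arrays correlated over 45 pairs of groups with a median of 0.00194 (-0.146 to 0.201). With the replicate number as a block the counts were 756 for mean silencing, 241, 204, 865, 878 and 495 in the 5 populations, 94, 199 and 168 for stem differences and 800, 480 and 26 for interactions, with 12, 5 and 1 lists. Among genes named by size the block ended the calls of ANKRD30A, CSF1 and URB1 in the mean interaction and no other.

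Among 157 values of genes named always or by size, quantile normalization ended 1 call and made 1, cyclic loess made 1, array weights ended 4 and made 2, and the arrays compared alone ended 15. Over 3 populations 6 of 24 were lost, and 158 of 1416 values with 1 array left out. For 358 values of further list members these were 49 ended and 11 made, 55 and 14, 10 and 24, and 94 and 3, with 23 of 47 and 485 of 2588 lost. No value of either kind reversed apart from the 4 given. Alternatives for probe sets named RARB were not run, as there was none.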

Other observations

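The test of PNO1 was chosen only after the result was seen, and so were the genes named next, by their calls in several populations. Of 7 genes that rose in 3 populations, CEACAM6, the contactin-associated protein gene CNTNAP3B, FCGBP and the synaptic vesicle priming gene UNC13A rose in parental, CD166-EpCAM- and CD166+CD44+ cells and fell in CD166-CD44- cells. CNTNAP3B differed by 1.23, 0.93 and 0.80 in the first 3 and by -1.33 in the last. PTGES, the gene of a prostaglandin E synthase, rose by 0.92, 0.96 and 1.00 in parental, CD166+EpCAM+ and CD166-CD44- cells. HOXB5, a homeobox gene, rose by 0.98, 0.72 and 0.57 in parental, CD166+EpCAM+ and CD166-EpCAM- cells, and the seventh gene was NID2. Of the 7 only CEACAM6 and NID2 kept each call in the EpCAM sort with its silenced labels exchanged. A call in one population and not in another does not show that they differ, and populations were tested against each other pair by pair only within a sort.

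Among 37519 probe sets without a gene symbol, tested by themselves with limma, 45 were higher and 153 lower in the mean effect of silencing. In parental cells 67 were higher and 12 lower, in CD166+EpCAM+ 71 and 197, in CD166-EpCAM- 130 and 261, in CD166+CD44+ 180 and 268 and in CD166-CD44- cells 27 and 103. Between unsilenced stem and non-stem cells 107 were higher and 38 lower in the EpCAM sort and 19 and 62 in the CD44 sort. The difference of the CD44 transcript between the silencing effects in stem and non-stem cells of the EpCAM sort was -0.66 (adjusted p = 0.0777) and ranged over the alternatives from an adjusted p of 0.018 after cyclic loess to 0.213 without silenced CD166+EpCAM+ replicate 1, and with exchanged labels it was 0.33 (0.508).

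A hypothesis from the accession beside the shRNA target is that the construct lowered PNO1, the gene to which it belongs. Of 500 genes of similar level 5.8% had as low a mean change (exact 95% interval 3.92 to 8.22), around the bound of 5% set for the test, so the hypothesis is undecided. The median change of those genes was -0.0962, against -0.29 for PNO1. Whether RARB fell, or the virus acted by itself, was not tested.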
